A study of Homo sapiens with 6 samples.

How the data were processed

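Gene expression was measured on Affymetrix arrays in 6 skin lesions of erythema nodosum leprosum (ENL), an acute inflammatory complication of leprosy. The biopsies were taken before the start of treatment, frozen, and cut into cryosections for total RNA extraction with a column kit, per the labels. All 6 lesions belong to 1 group, and lesions are numbered 1 to 6 here only as names. The numbers follow the order of the deposited columns and differ in part from those in the submitters' sample titles. The labels do not say in words that each lesion came from a different patient. P-values therefore describe these samples and not patients at large. Those of the list and variance tests compare genes, and those of the pairs of scores compare lesions. The labels name both Cy3 and Cy5, although the deposited table holds a single value per probe set and sample.

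The deposited values are intensities on a linear scale, 1 column per lesion. The submitters' processing notes name RMA (background correction, quantile normalization and summary of probes) with no version. RMA gives log2 values, so the deposited values had been returned to a linear scale. Whether other arrays were normalized together with these 6, and by which rule the listed probe sets were chosen, is not given in the sources used here. The table lists 13688 probe sets, and a gene or probe set outside it was not analysed here. Of these, 12178 were paired with 1 gene in the platform annotation, 665 with several genes and 845 with none, and only the first kind was used. Entrez identifiers of 12175 of them were found in the RefSeq table of GRCh38.p14, which changed 0 symbols. XIST and Y-linked genes (7 probe sets) were left out.

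Each value was taken as log2(intensity + 1). Fold differences are on that scale and understate differences of dim genes. Where a named gene's lowest lesion lay below the detection level, its fold is the highest lesion over that level, written as a minimum. Folds of list scores are of the measured values. Each gene was represented by its probe set with the highest mean, which gave 8465 genes. Among 98 genes of the fixed lists with several probe sets, the median of the lowest correlation between probe sets over the lesions was 0.954, and 3 genes had a negative value. The detection level was planned as the 95th percentile of the lesion means of probe sets for 52 genes restricted to other organs. Only 2 of those genes were listed, so the level (an intensity of 165, or 7.37 on the log2 scale) rests on 2 probe sets and is no more than an intensity limit. It left 7242 genes. Analyses were repeated with no such limit.

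The design, the gene lists and the alternatives were fixed before the data were examined. There were 44 lists, 26 of cell type markers and 18 of pathways, with 568 genes, of which 369 were listed and 278 lay above the detection level. Lists with at least 5 genes above the level were tested (24 lists). The median SD of a list's genes over the 6 lesions was set against 10000 random lists of equal size matched on mean level in 20 bins, two-sided. The mean pairwise Pearson correlation of a list's genes was set against the same random lists, one-sided. Both were adjusted by the Benjamini-Hochberg method over the 24 lists. The smallest unadjusted p these random lists can give is 0.0002 for spread and 0.0001 for covariation. These tests draw genes, not patients, and genes are not independent replicates. A list score is the mean over the list's genes of the log2 deviation from the gene's mean over the 6 lesions, so a score of 1 is 2-fold above that mean. Of 12 pairs of list scores fixed in advance, 11 could be computed. Each was tested with an exact two-sided permutation test over 720 pairings. With 1 exception, the endothelial value in a test of an explanation, which stands beside those of the other lists tested, no pooled correlation is given where a score fell into separate clusters, taken as a gap of over 50% of its range with at least 2 lesions on either side. That rule was added after the scores were seen and was judged over all 6 lesions. With lesions left out, the rest can fall into such clusters, and a correlation then says little beyond that split.

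Each gene's variance was tested against the prior variance that limma 3.58.1 (R 4.3.3) fits at its mean level, robustly and with a trend, from 5 degrees of freedom per gene, with Benjamini-Hochberg adjustment over all genes. The lists were also tested adjusted over the list alone. Other computations used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3. On simulated data of 7242 genes with a prior as wide as the one found here (3 degrees of freedom), the variance test recovered 0% of 200 genes with an 8-fold SD. With a narrow prior (20 degrees of freedom) it recovered 96.5% of them. The list tests recovered 92% of simulated lists for spread and 96% for covariation, where the genes of a list had a 3-fold SD and a shared factor. They also called 2% and 6% of unchanged lists. The other simulated genes were independent, unlike the genes here, so these rates may not carry over.

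Genes are named by a rule fixed in advance: the 15 genes above the level with the largest SD after genes that can follow a germline genotype were left out, the genes of each list with the highest mean, largest SD and smallest SD, and a set of 47 genes chosen from knowledge of leprosy. Of that set 32 were listed and 24 lay above the level. Genes whose level can follow a germline genotype (HLA class I, HLA-DQ and HLA-DR beta genes among them) were not named. Alternatives were the scaling of the arrays, the choice of probe set, the filter on dim genes, the summaries of spread and correlation, and leaving out each lesion. The number of arrays limits the precision of every value. Probe sets differ in affinity, so the choice of a list's gene with the highest mean reflects the probe sets as well as abundance.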

Results

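Erythema nodosum leprosum lesions were profiled in a study of cell types and immune pathways behind host defence and immunopathology in leprosy, an infection of skin and nerve by Mycobacterium leprae. The data comprised 6 ENL skin lesions and no other group. Lesions of other forms of leprosy were not analysed here, so the values below describe what was present in ENL lesions and how far these lesions differed from each other. The median intensity per lesion lay between 301 and 322. Over all probe sets on the log2 scale, the correlation between lesions ranged from 0.787 (lesions 1 and 6) to 0.956 (lesions 3 and 4), across probe sets that are not independent replicates.

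Single genes differed by large factors between the 6 lesions. CCL8, a monocyte chemoattractant, had the largest SD (9.07 ± 3.05, mean log2 intensity ± SD, n = 6) and spanned at least 25-fold between lesions, taken against the detection level because its lowest lesion lay below it. CXCL10, a chemokine induced by interferons, spanned at least 60.5-fold (10.05 ± 3.03). FLG (filaggrin, 8.63 ± 2.80) spanned at least 26.3-fold and LORICRIN (9.31 ± 2.76) at least 50.4-fold, both structural proteins of the cornified layer. After 1 gene whose level can follow a germline genotype was left out, the other genes among the 15 with the largest SD were PRR9, IDO1, FLG2, PTX3, SELE, KRTAP11-1, KRTAP4-9, GBP5, KRT25, KRTAP1-5 and SPRR1A. PRR9, KRTAP11-1, KRTAP4-9, KRTAP1-5 and the hair follicle list gene KRT25 were highest in lesion 1, as were FLG, LORICRIN, FLG2 and SPRR1A. The hair follicle score, of 4 genes with KRT25 among them, was also highest there (3.17). The median SD over 7242 genes was 0.29, and 293 genes had an SD above 1. The first principal component held 52.2% of the variance. With limma's prior variance and Benjamini-Hochberg adjustment, 0 genes varied more than their level predicted (smallest adjusted p = 0.884), and 402 genes had an unadjusted p under 0.05, where chance gives 362. In simulated data that test recovered 0% of changed genes at this width of the prior, so it does not separate genes here.

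Of the 24 gene lists tested, 16 had a larger spread between lesions than random lists matched on level, and 0 had a smaller one. In 16 lists the genes varied together, 12 of them among those with a large spread. The reference genes, used as an unregulated background, had a median SD of 0.27 against 0.28 for random lists (adjusted p = 0.71, random-list test), and their score spanned 1.26-fold. That score was -0.08, -0.14 and -0.09 in lesions 1, 2 and 5, and 0.07, 0.19 and 0.04 in lesions 3, 4 and 6. Though small, this difference divided the lesions as the interferon-gamma and cytokine scores below did. Its cause was not tested.

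**Figure D1:**
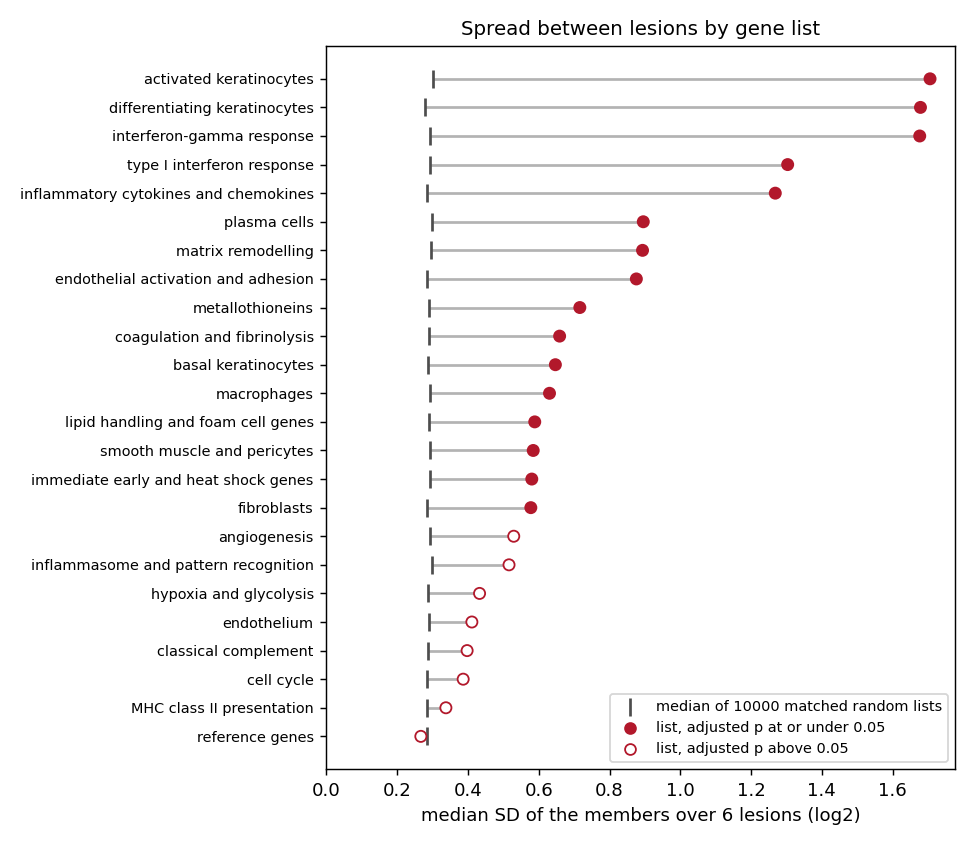
Median SD over the 6 lesions (log2, x axis) of the genes of each of 24 lists (y axis), with filled points for lists at an adjusted p of 0.05 or lower, open points for the other lists, and ticks for the median of 10000 matched random lists. Activated keratinocytes, differentiating keratinocytes and the interferon-gamma response lie farthest from their random lists, and the reference genes lie at 0.27 against 0.28.

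Interferon-inducible genes varied together and over a wide range. The interferon-gamma response score spanned 16.7-fold between lesions (median SD 1.68 against 0.29 in random lists, adjusted p = 0.0008; mean correlation between genes 0.94, adjusted p = 0.00024). It was lowest in lesion 1 (-2.27), lesion 2 (-1.23) and lesion 5 (-0.92), and it reached 0.94 in lesion 3, 1.70 in lesion 4 and 1.79 in lesion 6. CXCL9, which attracts T cells, ranged from 7.49 in lesion 1 to 13.07 in lesion 4. IDO1, which degrades tryptophan, ranged from 6.38 in lesion 1 to 12.65 in lesion 6. GBP5, a guanylate-binding protein, spanned at least 13.7-fold. GBP2, the list's least variable gene, still spanned 5.50-fold (10.36 ± 0.96), and WARS1, its gene with the highest mean, 16.1-fold. All 12 genes of the list passed the variance test adjusted over the list alone and 0 passed it over all genes. A list whose genes all have an unadjusted p under 0.05 passes whole when adjusted alone. Such counts, here and below, therefore restate large SDs and are no separate support. The type I interferon response score spanned 7.14-fold (median SD 1.30, adjusted p = 0.0008), from -1.35 in lesion 1 to 1.49 in lesion 4. RSAD2, an antiviral enzyme, spanned at least 7.70-fold and MX2 2.97-fold. Of its 16 genes, 9 passed adjusted over the list alone and 0 over all genes. The metallothionein score, of metal-binding stress proteins, spanned 3.09-fold (mean correlation 0.94, adjusted p = 0.00024). Its spread call (adjusted p = 0.0055) was lost without lesion 1 (adjusted p = 0.06). ADIPOQ, an adipocyte gene singled out after its values were seen and below the detection level on average, was at 8.29, 8.33 and 8.19 in lesions 1, 2 and 5, and at 3.93, 4.01 and 4.18 in lesions 3, 4 and 6. FABP4, which adipocytes also express, divided the same way (9.67 or above against 7.78 or below), as did the score of the 4 listed adipocyte genes with no limit on dim genes (0.67, 0.71 and 0.76 against -0.72, -0.72 and -0.71). The exception was CFD (adipsin), that list's only gene above the level, at 10.62, 9.83 and 10.75 in lesions 1, 2 and 5, and at 10.74, 10.87 and 10.36 in lesions 3, 4 and 6.

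Inflammatory cytokines and chemokines showed 2 separate levels. The list's score was -1.47, -1.11 and -0.87 in lesions 1, 2 and 5, against 1.23, 1.09 and 1.13 in lesions 3, 4 and 6 (median SD 1.27, adjusted p = 0.0008; mean correlation 0.86, adjusted p = 0.00024). IL6 ranged from 4.79 in lesion 1 to 9.64 in lesion 3, at least 4.82-fold. IL1B spanned at least 4.66-fold (7.99 ± 1.27), CXCL8, a neutrophil chemoattractant, at least 4.95-fold (8.08 ± 1.03), and the receptor antagonist IL1RN 6.97-fold (10.65 ± 1.13). The adipocyte score with no limit on dim genes divided the lesions in the same way, at 0.67 or above in lesions 1, 2 and 5 and at -0.71 or below in the others, as did ADIPOQ and FABP4 but not CFD. All 7 cytokine genes passed the variance test adjusted over the list alone and 0 over all genes. PTX3, an acute-phase pattern recognition molecule, ranged from 6.09 in lesion 2 to 12.28 in lesion 4. S100A8 (12.44 ± 1.61) and S100A9 (9.89 ± 2.04), calcium-binding proteins of neutrophils, monocytes and activated keratinocytes, were lowest in lesion 1 and highest in lesion 4. Endothelial activation and adhesion genes had a median SD of 0.88 (adjusted p = 0.0014) and a mean correlation of 0.49 (adjusted p = 0.007). The latter call was lost without lesion 4 (mean correlation 0.24, adjusted p = 0.06) and without lesion 6 (0.18, adjusted p = 0.12). SELE, the endothelial selectin that captures leukocytes, ranged from 4.59 in lesion 2 to 10.68 in lesion 3. VCAM1 spanned 4.66-fold and ICAM2 1.77-fold. In that list 1 gene passed adjusted over the list alone. Of 18 neutrophil markers, 7 were listed and 4 lay above the detection level, too few for the list tests. LTF (lactoferrin) spanned 22.2-fold, FPR1, the formyl peptide receptor, at least 5.77-fold, and FCGR3B, an Fc receptor of neutrophils, at least 5.55-fold. Each was highest in lesion 6. With no limit on dim genes the 7 neutrophil genes had a median SD of 0.99 (adjusted p = 0.0063) and a mean correlation of 0.51 (adjusted p = 0.0022).

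Genes of the upper and of the basal epidermis both varied more than random lists. Differentiating keratinocyte genes had a score of 1.93 in lesion 1 and 1.80 in lesion 2, near 0 in lesion 4 (0.06) and lesion 3 (-0.26), -0.94 in lesion 6 and -2.60 in lesion 5, a 23-fold span (median SD 1.68, adjusted p = 0.0008; mean correlation 0.91, adjusted p = 0.00024). FLG2 spanned at least 37.2-fold, whereas KRT10, the least variable gene of the list, spanned 4.94-fold. All 11 genes passed the variance test adjusted over the list alone and 0 over all genes. Basal keratinocyte genes had a median SD of 0.65 (adjusted p = 0.0055). That call was lost without lesion 4 (adjusted p = 0.10) or lesion 5 (0.11), with probe sets averaged (0.083) and with no limit on dim genes (0.055). Their covariation (mean correlation 0.61, adjusted p = 0.0016) was lost without lesion 5 (0.11, adjusted p = 0.23) and with the probe set of largest SD (0.30, adjusted p = 0.0501). KRT14, the main keratin of basal cells, was at 13.75 ± 0.41 and KRT15 at 8.38 ± 1.67. Activated keratinocyte genes had a median SD of 1.71 (adjusted p = 0.0008), with a score of 1.36 in lesion 4 and -2.45 in lesion 5. KRT16, a keratin of injured and inflamed epidermis, ranged from 8.76 in lesion 5 to 12.96 in lesion 4. SPRR1A ran otherwise, from 11.48 in lesion 1 to 5.21 in lesion 5. The list's covariation (0.48, adjusted p = 0.015) was lost without lesion 3 (0.44, adjusted p = 0.053) without lesion 5 (0.17, adjusted p = 0.2) and by Spearman's correlation (0.35, adjusted p = 0.054). Lists of other skin structures had too few genes above the level to be tested. The hair follicle gene TCHH (trichohyalin) was at 12.20 in lesion 1 and 6.02 in lesion 2. The pigment cell gene TYRP1 ranged from 11.80 in lesion 2 to 6.78 in lesion 6, while ELOVL5 of the sebaceous gland list was at 10.61 ± 0.20.

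Macrophage and plasma cell genes were highest in lesion 5. The macrophage score was 0.92 there and between -0.62 and 0.10 in the other lesions (median SD 0.63, adjusted p = 0.0014; mean correlation 0.61, adjusted p = 0.00024), and 0 of its 13 genes passed the variance test over the list alone. CD163, a scavenger receptor, was at 10.17 ± 0.79 and reached 11.53 in lesion 5. The complement C1q genes C1QA (8.86 ± 0.63), C1QB (9.68 ± 0.61) and C1QC (8.78 ± 0.88) were also highest in lesion 5, as was CD209 (8.35 ± 0.60), a lectin of dermal macrophages and dendritic cells. AIF1 was highest in lesion 6. Plasma cell genes had a median SD of 0.90 (adjusted p = 0.0014), which was lost without lesion 5 (0.49, adjusted p = 0.1). IGHM, the IgM heavy chain, ranged from 5.72 in lesion 2 to 11.14 in lesion 5, with correlations between its 4 probe sets as low as 0.58. SDC1, which keratinocytes also express, went the other way, from 10.69 in lesion 2 to 8.38 in lesion 5. The plasma cell genes above the level did not vary together beyond random lists (mean correlation 0.16, adjusted p = 0.16), but the 12 listed ones did with no limit on dim genes (0.42, adjusted p = 0.00085). MHC class II presentation genes varied together (mean correlation 0.75, adjusted p = 0.00044) and did not pass the test of spread (median SD 0.34 against 0.28 in random lists, adjusted p = 0.54). CD74 was at 12.06 ± 0.30 and HLA-DPA1 at 12.64 ± 0.32, and CTSS (cathepsin S), the list's most variable gene, at 9.88 ± 0.64. Classical complement genes had a median SD of 0.40 (adjusted p = 0.18). Their covariation (0.31, adjusted p = 0.033) was lost without lesion 2 (0.028, adjusted p = 0.51), under quantile normalization (adjusted p = 0.067), by Spearman's correlation (0.064) and with either other choice of probe set (0.059 and 0.087). CFB spanned 9.40-fold and C1R 1.64-fold. Genes of lipid handling and foam cells, the lipid-laden macrophages of leprosy lesions, had a median SD of 0.59 (adjusted p = 0.0022) and a mean correlation of 0.19 (adjusted p = 0.061), which passed under quantile normalization (adjusted p = 0.0072), with array medians subtracted (0.015), probe sets averaged (0.043), no limit on dim genes (0.022), random lists not matched on level (0.033) and without lesion 2 (0.021). The list's score was 0.44, 0.19 and 0.36 in lesions 1, 2 and 5, and -0.30, -0.50 and -0.19 in lesions 3, 4 and 6, the division of the adipocyte score. FABP4, a fatty acid binding protein of adipocytes and macrophages, divided likewise and spanned at least 5.80-fold, while GPNMB spanned 2.82-fold and ACAT1 1.30-fold.

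Among the genes chosen from knowledge of leprosy, the vitamin D receptor gene VDR was at 9.45 ± 0.28, against a median SD of 0.29 over all genes. TLR2, a receptor for mycobacterial lipoproteins, spanned at least 3.62-fold (8.19 ± 1.04) and was highest in lesion 4. CYP27B1, which activates vitamin D (6.61 ± 0.37), and CD1B (5.34 ± 0.22), a lipid antigen-presenting molecule, lay below the detection level on average. GNLY (granulysin) was below it on average too, with 8.54 in lesion 6. IL15 was at 7.51 ± 0.61, GZMB at 7.84 ± 0.89 and PRF1 at 7.52 ± 0.76. Both cytotoxic genes were lowest in lesion 1 and highest in lesion 6. ARG1 (arginase), below the level on average, was at 9.47 in lesion 1 and 9.83 in lesion 2, and between 3.82 and 5.30 in the other lesions. The differentiating keratinocyte score, with FLG and LORICRIN among its genes, was also highest in lesions 1 and 2. MMP9 was highest in lesion 2 (10.58), and the other lesions lay between 8.42 and 9.40.

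Stromal scores were highest in lesion 1. The fibroblast score was 1.07 there, 0.38 in lesion 2 and 0.27 in lesion 5, and -0.52, -0.69 and -0.51 in lesions 3, 4 and 6 (median SD 0.58, adjusted p = 0.0014; mean correlation 0.59, adjusted p = 0.00024). ADIPOQ (8.19 or above in lesions 1, 2 and 5, 4.18 or below in the others), FABP4 (9.67 or above, 7.78 or below) and the adipocyte score followed the same division, and CFD did not. POSTN (periostin) spanned 21.2-fold and COL3A1 2.49-fold. Smooth muscle and pericyte genes varied together (0.75, adjusted p = 0.00024), and their spread (median SD 0.58, adjusted p = 0.016) was lost without lesion 4 (adjusted p = 0.089). RGS5, a pericyte gene, ranged from 11.15 in lesion 1 to 7.08 in lesion 4. Endothelial cell genes did not pass the test of spread (median SD 0.41 against 0.29 in random lists, adjusted p = 0.15) but varied together (0.31, adjusted p = 0.007). PECAM1 was at 10.89 ± 0.46, although correlations between its 4 probe sets went as low as -0.51. Matrix remodelling genes spread widely (median SD 0.89, adjusted p = 0.0008) without varying together (0.07, adjusted p = 0.28), with MMP3 (stromelysin) at 4.70-fold or more and MMP14 at 1.71-fold or more. Coagulation genes behaved likewise (median SD 0.66, adjusted p = 0.0036; mean correlation -0.01, adjusted p = 0.59), and F13A1, expressed by dermal macrophages and dendrocytes, was lowest in lesion 6 (6.97). Cell cycle genes varied together (0.59, adjusted p = 0.00024) within a 1.73-fold span. Immediate early and heat shock genes, which respond to handling of tissue as well as to inflammation, had a median SD of 0.58 (adjusted p = 0.0074), and their covariation (0.51, adjusted p = 0.00024) was lost without lesion 5 (0.11, adjusted p = 0.2). Angiogenesis (median SD 0.53, adjusted p = 0.068), inflammasome (0.52, adjusted p = 0.072) and hypoxia genes (0.43, adjusted p = 0.073) did not pass the test of spread. Hypoxia genes passed it without lesion 1, 3, 5 or 6 (adjusted p = 0.026, 0.045, 0.02 and 0.011) and inflammasome genes without lesion 2, 3 or 5 (0.028, 0.041 and 0.032).

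**Figure D2:**
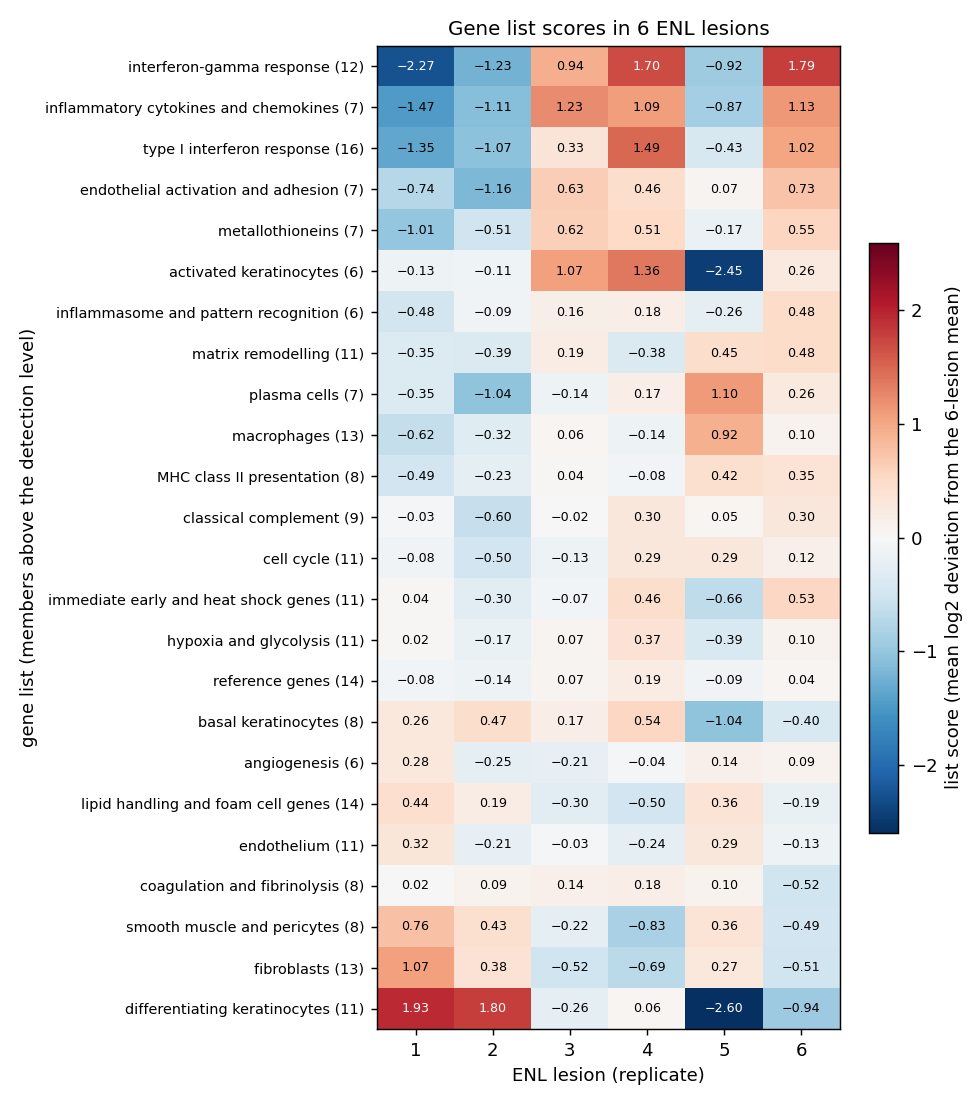
Scores of the 24 tested gene lists (rows, with the number of genes above the detection level) in the 6 ENL lesions (columns), as mean log2 deviation from the mean of the 6 lesions, ordered by the list's loading on the first principal component. The interferon-gamma response runs from -2.27 in lesion 1 to 1.79 in lesion 6, and the differentiating keratinocytes from 1.93 in lesion 1 to -2.60 in lesion 5.

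Pairs of list scores asked which of these programmes went together across lesions. Of 11 pairs computed, 6 involved a score in separate clusters, and no pooled correlation is given for them. These were the pairs of the inflammatory cytokine score with the neutrophil, matrix remodelling and immediate early scores, both pairs of the T cell score, and the pair of endothelium with smooth muscle. Of the other 5, 3 passed the exact permutation test after Benjamini-Hochberg adjustment over the 11 pairs. The macrophage and differentiating keratinocyte scores ran in opposite directions (r = -0.95, exact p = 0.0014, the smallest the 720 pairings allow, adjusted p = 0.015; Spearman's rho = -1, exact p = 0.0028, adjusted p = 0.031). Without lesions 1 and 5, the farthest from the median macrophage score, r was -0.95. The interferon scores rose together (r = 0.97, exact p = 0.0056, adjusted p = 0.031; rho = 0.94, exact p = 0.017, adjusted p = 0.092), with r = 0.98 without lesions 1 and 4. In the remaining lesions the interferon-gamma score fell into separate clusters (lesions 2 and 5 against 3 and 6), so that last value adds little. The 4 neutrophil genes went with endothelial activation and adhesion (r = 0.91, exact p = 0.012, adjusted p = 0.046; rho = 0.89, exact p = 0.033, adjusted p = 0.12), with r = 0.94 without lesions 1 and 6. The adjusted p of these 3 pairs became 0.051 under quantile normalization. Without any 1 lesion, r stayed between -0.98 and -0.93, 0.96 and 0.98, and 0.89 and 0.94. The smallest exact p with 5 lesions is 0.0083, or 0.092 after adjustment if 1 pair reaches it, so calls lost there do not show a weaker relation. Plasma cell and complement scores did not pass (r = 0.70, exact p = 0.14, adjusted p = 0.24; rho = 0.77, exact p = 0.1, adjusted p = 0.19). Their r was 0.95 without lesions 2 and 5, 0.20 without lesion 2 alone and 0.98 without lesion 5 alone, so this pair is not settled either way. The test found no relation of macrophage and lipid handling scores (r = 0.03, exact p = 0.95, adjusted p = 0.95; rho = -0.20, exact p = 0.71, adjusted p = 0.79), with r = -0.51 without lesions 1 and 5 and -0.81 without lesion 5 alone, so 6 lesions do not settle it. Plasma cell and lipid handling genes above the level did not vary together beyond random lists, so their scores are weak summaries. The lipid handling score also divided the lesions as the adipocyte score did. The planned pair of plasma cells and B cells had 0 B cell genes above the detection level. With no such limit its r was 0.93 (exact p = 0.0083, adjusted p = 0.033) over 2 B cell genes, and rho was 0.83 (exact p = 0.058, adjusted p = 0.14). No batch is named in the labels, so no value within batches could be given.

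**Figure D3:**
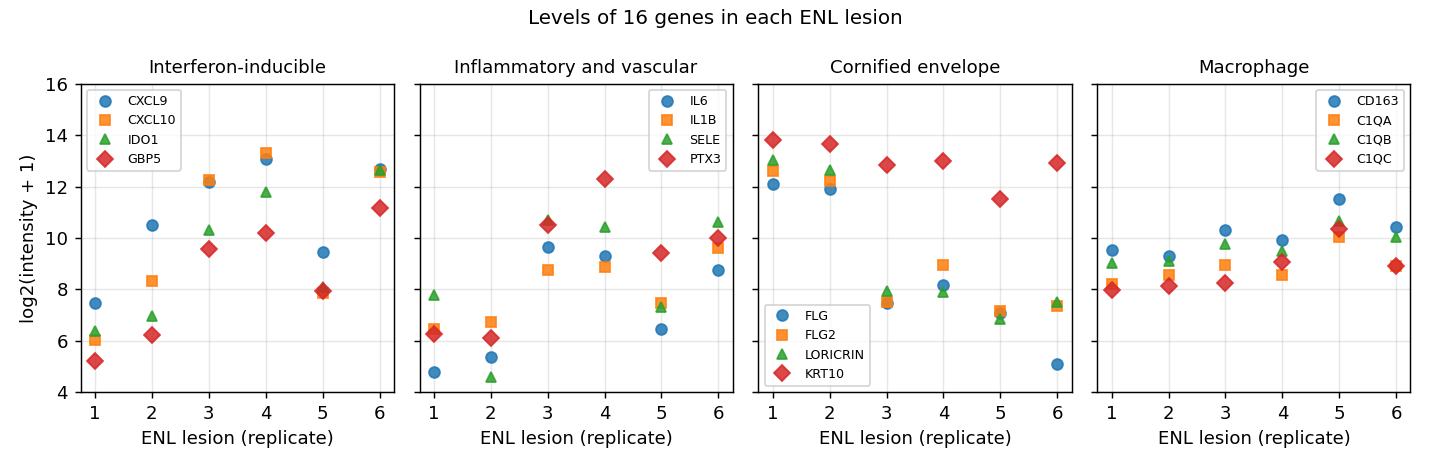
Level of 16 genes (log2(intensity + 1), y axis) in each of the 6 ENL lesions (x axis), 1 symbol per gene, in panels of interferon-inducible, inflammatory and vascular, cornified envelope and macrophage genes. CXCL10 lies between 6.02 and 13.29, FLG between 5.09 and 12.09, and CD163 is highest in lesion 5 at 11.53.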

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

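The tests of explanations in this part were chosen after the scores were seen, except both tests of array scaling. Among 170 values examined over the 6 lesions (40 list scores, 129 genes and the array median), 5 had a single lesion set apart from the others by Dixon's 95% criterion for 6 samples, the gap to the nearest lesion divided by the range. Chance flags about 1 in 20, or 8.5 of 170. The classical complement score was lowest in lesion 2 (-0.60, with the next at -0.03; gap 0.636 of the range). The coagulation and fibrinolysis score was lowest in lesion 6 (-0.52, next 0.02; gap 0.763). The cell cycle gene CCNB2 was highest in lesion 4 (7.99, next 7.47; gap 0.746). LAMB3, a basement membrane laminin chain, was lowest in lesion 5 (6.62, next 7.33; gap 0.634). MUCL1, a sweat gland gene, was lowest in lesion 5 (8.78, next 10.29; gap 0.658).

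The interferon-gamma response score spanned 4.06 log2 units between lesions of 1 diagnosis. The span was 3.98 after quantile normalization, which argues against scaling differences left between the deposited arrays. The submitters' notes already name quantile normalization, so a second round could change little, and effects of the first were not tested. Dilution of all dermal transcripts alike by epidermis or fat (fat was added to this explanation after the adipocyte genes were seen) would make fibroblast and interferon scores fall together, and they ran in opposite directions (r = -0.976, between -0.988 and -0.969 without any 1 lesion). This speaks only to dilution that acts on all dermal transcripts alike. The adipocyte score, though not CFD, was higher in the lesions with the lower interferon scores, so the share of fat itself stays open. A larger number of cytotoxic lymphocytes could contribute: with no limit on dim genes their score had r = 0.388 with the interferon-gamma score (0.0097 to 0.838 without any 1 lesion), and 6 lesions leave this open. Displacement of stroma by infiltrate, stage of the lesion and the site or depth of the biopsy were not tested and stay open.

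Differentiating keratinocyte genes had a larger median SD than basal ones (1.68 against 0.65). Exchanging genes between the lists in all 75582 ways rarely gave a difference of 1.03 or more (exact permutation p = 0.0015, 0.0012 to 0.017 without any 1 lesion). That test exchanges genes as if independent, but they varied together within each list (mean correlation 0.91 and 0.61). Its p-values, here and below, can therefore be too small. A different share of epidermis in the sections would move both lists alike, but the first test of it was void, since SDs of 1.71 and 0.61 allow the difference between the scores, with an SD of 1.24, none under 1.11. Without the 5 genes near the detection level or at the top of the range the difference was 0.80 (exact permutation p = 0.05) and 0.53 without lesion 5 (exact permutation p = 0.16), so that share stays open. Scaling differences left between the deposited arrays are argued against by a span of 4.46 after quantile normalization and 4.53 before it. This test too had little room, because the submitters' notes already name that step. The bright basal keratin KRT14 may be near the top of the array's range, which would hide part of its change, and a change in epidermal differentiation remains a hypothesis.

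The macrophage and differentiating keratinocyte scores ran in opposite directions. The relation did not rest on lesion 5, with the highest macrophage score, since r was -0.929 without it (exact permutation p = 0.025, adjusted p = 0.092). More dermis and less epidermis in some sections may give such a relation. Fibroblast genes, which would then also run opposite to the keratinocyte genes, had r = 0.444 with them (0.043 to 0.894 without any 1 lesion). Endothelial genes had r = -0.194 (-0.837 to 0.430) with a score in separate clusters, and smooth muscle genes, added after that value was seen, had r = 0.335 (-0.00081 to 0.860), so this explanation and more infiltrate per section stay open.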

How the results depend on the processing

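No paired analysis was possible because the design has 1 group. The count of genes varying more than their level predicted was 0 under every alternative run, including no trend and a prior that was not robust. Of the 16 lists with a large spread, 12 passed under all alternatives run, and of the 16 varying together, 11 did. The lists that lost a call are named with the results above. The number of lists was 16 to 19 for spread and 14 to 18 for covariation without any 1 lesion. With no filter on dim genes, 34 lists could be tested, and 20 were called for spread and 28 for covariation. The count of genes with an SD above 1, added after seeing the data, was 246 to 346 without any 1 lesion, and 264 to 283 list genes lay above the detection level. The first component held 47.7% to 67.6% of the variance without any 1 lesion and 39.8% with genes scaled to unit SD. Of the 3 pairs that passed, 0 passed under quantile normalization (r = 0.904 for neutrophils with endothelial activation, 0.970 for both interferon scores, -0.898 for macrophages with differentiating keratinocytes). With reference genes subtracted 1 passed (0.889 and -0.843 for the first and last pair), and by Spearman's correlation 1 passed (0.886 for the first, 0.943 for the interferon scores). The neutrophil pair also missed the threshold with probe sets averaged (0.911), members scaled (0.848) and without its 2 farthest lesions (0.942). Leaving out 2 lesions leaves few pairings, and r was then above the 0.910 of all lesions. That last miss does not show a weaker relation. Without any 1 lesion, 0 to 2 pairs passed, but 5 lesions allow no exact p under 0.0083. The correlations then ranged from 0.890 to 0.943 for neutrophils, 0.961 to 0.980 for the interferon scores and -0.980 to -0.929 for macrophages with keratinocytes. The range was 0.197 to 0.977 for plasma cells with complement. Macrophages with lipid genes ranged from -0.810 to 0.489, with -0.063 without lesion 4, and were -0.200 by Spearman's correlation and -0.514 without the 2 farthest lesions. Uncalled list values near 0 also changed sign. The reference genes' median SD was above the random lists at 0.287 under quantile normalization, and ranged from 0.251 to 0.281 without any 1 lesion. The mean correlation of coagulation genes was 0.0010 with probe sets averaged, 0.0024 with no filter, 0.010 by Spearman's correlation and -0.117 to 0.050 without any 1 lesion. It was -0.0073 for matrix remodelling with no filter, and -0.127 to 0.055 for angiogenesis without any 1 lesion. The cause of these changes was not tested, beyond fewer lesions where some were left out. Signal over background could not be assessed, and genes near or under an intensity of 165 are the least certain.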

Other observations

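Except for the planned pair of T cells with the interferon-gamma response, the relations in this part were chosen after the scores were seen. With no limit on dim genes, cytotoxic lymphocyte genes (11 listed) varied together (mean correlation 0.67, adjusted p = 0.00031) and so did T cell genes (12 listed, 0.74, adjusted p = 0.00031). The T cell score was 0.55, 0.38 and 0.30 in lesions 3, 5 and 6, and -0.35, -0.38 and -0.49 in lesions 1, 2 and 4. The exact permutation test of this score with the interferon-gamma score did not pass (exact p = 0.62, adjusted p = 0.68), and no pooled r is given because the T cell scores fall into separate clusters. Mast cell genes (6 listed, mean correlation 0.63, adjusted p = 0.0016) were highest in lesion 1 (1.12) and lowest in lesion 4 (-0.57). Hair follicle genes (8 listed, median SD 2.02, adjusted p = 0.00076) had a score of 3.03 in lesion 1 and of 0.43 or less in the others. The adipocyte score (4 listed genes) was 0.67, 0.71 and 0.76 in lesions 1, 2 and 5, and -0.72, -0.72 and -0.71 in lesions 3, 4 and 6, although its brightest gene CFD lay between 9.83 (lesion 2) and 10.87 (lesion 4). HBB, the haemoglobin beta chain, ranged from 6.46 in lesion 3 to 11.79 in lesion 6.

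Stromal scores ran opposite to the interferon-gamma score in these 6 lesions. The p-values below are adjusted over only the 9 relations picked with the scores in view. They do not account for that choice and are descriptive. Over 9 relations computed after the scores were seen, r with the interferon-gamma score was -0.976 for fibroblasts (exact p = 0.0056, adjusted p = 0.021; rho = -0.83, exact p = 0.058, adjusted p = 0.175) and -0.976 for smooth muscle and pericytes (exact p = 0.0069, adjusted p = 0.021; rho = -0.94, exact p = 0.017, adjusted p = 0.15). Without lesions 1 and 4, the 2 farthest, r was -0.97 and -0.9995. Lesions 2 and 5 then lay apart from lesions 3 and 6 in the fibroblast, smooth muscle and interferon-gamma scores. These values therefore give no separate support. Fibroblasts, smooth muscle and endothelium with differentiating keratinocytes, and cytotoxic lymphocytes with the interferon-gamma score, did not pass (adjusted p = 0.60 to 0.73). Basal and differentiating keratinocytes did not pass after adjustment (r = 0.85, exact p = 0.029, adjusted p = 0.066; rho = 0.77, exact p = 0.10, adjusted p = 0.23), with r = 0.12 without lesions 5 and 6. Metallothioneins ran with the interferon-gamma score (r = 0.96, exact p = 0.0069, adjusted p = 0.021; rho = 0.83, exact p = 0.058, adjusted p = 0.175), with r = 0.92 without the 2 farthest lesions. Lesion 5 then lay apart from lesions 3, 4 and 6 in both scores, so that last value adds little. A candidate explanation is that infiltrate takes the place of stroma in the more inflamed lesions. Macrophage and fibroblast scores were mixed on this. Both were above their means in lesion 5 (0.92 and 0.27) and below them in lesion 4 (-0.14 and -0.69). In lesions 1, 2, 3 and 6 they lay on opposite sides of their means. The macrophage score had r = 0.21 with the interferon-gamma score (exact p = 0.73, adjusted p = 0.73; rho = 0.60, exact p = 0.24, adjusted p = 0.36), with r = 0.91 without lesion 5, -0.27 without lesion 1 and 0.77 without both, so 6 lesions leave this open. No test here separates this explanation from the depth of the biopsy.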
